A study of Mus musculus with 8 samples.

How the data were processed

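RNA sequencing of 8 mouse liver samples was analysed. Per the labels, age-matched male mice had received the liver carcinogen diethylnitrosamine (DEN) and tissue was taken 8 months later. Per the labels, mice had been injected with a pT3 vector plasmid or with a pT3 plasmid carrying mouse APOBEC3B, while the sample titles say mA3. Mouse Apobec3 was taken as the gene meant. Each of 4 mice gave a tumour sample and a sample of non-tumour liver, called adjacent here, so that 4 groups held 2 libraries each. Nothing in the labels says that the mice are separate animals beyond their numbering, and p-values therefore measure the spread between these samples.

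Per the labels' protocols, total RNA was extracted with Trizol from flash-frozen tissue, its integrity was measured on an Agilent Bioanalyzer, and standard Illumina libraries were sequenced. The deposited table gives, per the file headers, a read count and an FPKM value (fragments per kilobase of gene, scaled to library size) for each of 34745 genes in each of the 8 libraries, with gene identifiers, symbols and positions. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here. Every deposited count was a whole number. In all 7555 genes with at least 100 counts in every library, the deposited FPKM values divided the counts by the library's summed counts and by 1 gene length, the same in every library within 1%. The FPKM values thus matched these counts. Neither check could show a scaling of the counts before the FPKM values were computed, such as a factor per library with rounding. The submitters' processing notes name genome build mm8 and Agilent Feature Extraction 10.7, which is microarray software. The positions in the deposited table were those of a later build. Of the 34745 gene identifiers, 34267 were in GENCODE vM21 (build GRCm38), all of them on the same chromosome, and 81.6% of those had a start and an end within 1 bp of it. Positions are given here as the deposited table gives them, with GRCm38 as the build found by this match.

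Total counts per library ran from 12969929 to 22882531. The counts were analysed with edgeR 4.0.16 under R 4.3.3. Genes were kept with filterByExpr by group (15009 genes) and libraries were scaled with TMM factors. A quasi-likelihood model with 1 coefficient per group was fitted to all 8 libraries, which left 4 residual degrees of freedom. The biological coefficient of variation was 39.1%. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Standard errors of log2 differences were derived from the quasi-likelihood F statistic. Levels are given as CPM, that is counts scaled to a common library size with TMM factors.

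6 comparisons were made. Tumour was compared with adjacent liver over both plasmids, within vector mice and within mA3 mice. The mA3 mice were compared with vector mice in tumour and in adjacent liver. An interaction tested whether the tumour difference itself differed between plasmids. Of 48 gene lists written from general knowledge before the data were examined, 47 had at least 5 tested members. They were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the lists. A list is described as called when this adjusted p was under 0.05. Camera compares a list with all other genes. The same test with a correlation estimated from the data was run beside it, and so was fry, which asks whether a list's genes move, on balance, in 1 direction. A gene can be on more than 1 list. For each list described, the members past the threshold over all genes and those adjusted over the list alone were counted. Lists of cell-type markers were read as lists of markers in bulk tissue.

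The comparisons, the tests, the lists and the rule for naming genes were fixed before the data were examined. Apobec3 was always named. For each comparison, up to 10 rising and 10 falling genes were then named that had the largest log2 difference among those passing, provided that the libraries of the groups did not overlap and the mean over the 8 libraries was at least 5 CPM. Predicted genes, Riken and accession-like symbols and pseudogenes were left out. Where fewer than 5 genes passed in a direction, the 5 with the smallest p under the same conditions were named as not passing. Up to 4 members with the smallest p were named from each list described. A gene named outside this rule is said to have been chosen after its values were seen.

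The labels number the mice, and the tumour and adjacent libraries that share a plasmid and a number are paired through the mouse. After group means were subtracted, the deviations of such paired libraries correlated across genes at 0.107 in vector mice and 0.175 in mA3 mice. The model above did not use the pairing. A fit with the mouse as a block was an alternative for the comparisons of tumour with adjacent liver and for the interaction. The comparison of mA3 with vector mice has no mouse in common, so that a fixed mouse block could not be fitted there.

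The alternatives fixed in advance were RLE and upper-quartile factors, no filter on low counts (23237 genes), a mean of at least 5 CPM (9824 genes), DESeq2 1.42.0, limma-voom, a fold change of at least 1 on the log2 scale, a fit of only the groups compared, each library left out in turn, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 0.5 (11812 genes), and the mouse as a fixed or a random block. Added after the data were seen were the list tests, the list medians and the adjustment of Apobec3 over its list alone with each library left out, and fits without both libraries of vector mouse 9. With a library left out, its group holds a lone library, which is assumed to vary like the other groups.

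The gene test was tested on simulated counts drawn from the means and library sizes of the real samples, with known changes. In the simulated comparison over both plasmids (14674 genes), 2.99% of genes changed 2-fold, 53.7% of those changed 4-fold and 87.9% of those changed 8-fold were found. The shares were 0%, 11.9% and 53.0% for tumour against adjacent in vector mice (14654 genes), and 0%, 26.9% and 74.2% in mA3 mice (14672 genes). For mA3 against vector they were 1.49%, 22.4% and 57.6% in tumour (14659 genes), and 0%, 13.4% and 42.4% in adjacent liver (14694 genes). The simulated interaction found 0%, 1.49% and 9.09% (14671 genes). Unchanged genes made up 7 of 103 calls over both plasmids, 1 of 44 and 4 of 71 within vector and mA3 mice, 12 of 66 and 1 of 38 between plasmids in tumour and adjacent liver, and 5 of 12 in the interaction. The share of false calls thus exceeded the nominal 0.05 in several simulated comparisons. Each gene was simulated with the same spread in every group. The real libraries of a group correlated at 0.930 (vector adjacent), 0.912 (vector tumour), 0.961 (mA3 adjacent) and 0.973 (mA3 tumour). The simulated shares therefore may not hold for real groups that differ in spread. In the list test, a list whose members were shifted 2-fold was called in all 6 simulated comparisons, with 0 other lists called. With an estimated correlation its adjusted p ranged from 0.0175 to 0.242. Simulated genes were drawn independently of each other. These runs therefore could not show how often lists of correlated genes are called wrongly.

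11508 genes had no count in any library. Genes with near-identical copies can share reads. The mitochondrial copy Gm28437 held 97.8% to 106% of the counts of mt-Co3 and Gm10925 held 145% to 168% of those of mt-Atp6. Values of the Mup, Ugt1a, Cyp2a, Cyp4a and H2-Q families are uncertain for the same reason. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 was used for the figures.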

Results

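Messenger RNA levels were measured by RNA sequencing in liver tumours and in adjacent non-tumour liver of male mice, 8 months after the carcinogen DEN. The series title names the effect of APOBEC3B on hepatocellular carcinoma, which is the question behind the comparisons of plasmids. Vector mice 1 and 9 and mA3 mice 1 and 2 each gave a tumour and an adjacent library. Total counts were 21967283 and 12969929 in vector adjacent 1 and 9, and 17997206 and 17988512 in vector tumour 1 and 9. They were 22076910 and 14311585 in mA3 adjacent 1 and 2, and 19838764 and 22882531 in mA3 tumour 1 and 2. Deposited read counts were compared with edgeR's quasi-likelihood test, adjusted over 15009 genes.

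Apobec3 encodes the mouse member of a family of cytidine deaminases that edit nucleic acids. The sample labels name a plasmid with mouse APOBEC3B and the sample titles say mA3. Mouse Apobec3 was taken here as the gene meant, which the labels do not state. The gene (ENSMUSG00000009585, protein coding) lies on the plus strand of chromosome 15 at 79891659 to 79915906 (GRCm38). Its level was 45.0 CPM in mA3 adjacent 1 and 35.1 CPM in mA3 adjacent 2, against 2.71 CPM in vector adjacent 1 and 9.96 CPM in vector adjacent 9. The libraries labelled mA3 tumour held 10.6 CPM (mouse 1) and 15.3 CPM (mouse 2), and vector tumour 1 and 9 held 7.85 and 15.2 CPM. Between the adjacent groups the log2 difference was 2.67 ± 0.62 (SE, n = 2 libraries per group), with an edgeR adjusted p of 1. Adjusted over the list alone, a list of 2 tested deaminase genes, it passed (adjusted p = 0.00485), and did so with each of the 8 libraries left out (0.000466 to 0.0254). The vector adjacent libraries were unlike each other, and the difference was 2.01 without vector adjacent 1 and 3.88 without vector adjacent 9. Between the tumour groups the log2 difference was 0.17 ± 0.58 (SE, n = 2; edgeR adjusted p = 0.909), so that Apobec3 did not separate the libraries labelled mA3 tumour from the vector tumours. It was -0.23 without vector tumour 1, 0.73 without vector tumour 9, 0.42 without mA3 tumour 1 and -0.12 without mA3 tumour 2. From adjacent to tumour, Apobec3 differed by 0.88 ± 0.59 in vector mice (adjusted p = 0.616) and by -1.63 ± 0.59 in mA3 mice (adjusted p = 0.175). The difference in vector mice was 0.21 without vector adjacent 1, 2.08 without vector adjacent 9 and 0.32 without vector tumour 9. Over both plasmids the difference was -0.37 ± 0.41 (adjusted p = 0.639), and 0.22 without vector adjacent 9. Gene counts do not separate transcripts of the plasmid from those of the endogenous gene. Directions drawn below from the libraries labelled mA3 tumour rest on their labels.

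**Figure D1:**
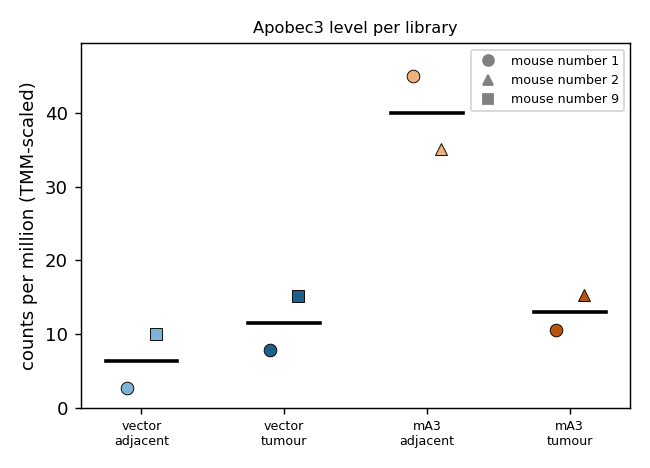
Apobec3 level per library in CPM with TMM-scaled library sizes (linear axis from 0), by group; points are libraries shaped by mouse number and bars are means of 2 libraries. The adjacent libraries of mA3 mice, at 45.0 and 35.1 CPM, lie above the other 6 libraries, which reach 15.2 or 15.3 CPM at most.

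Expression profiles separated most tumours from adjacent liver. The main axis of variation (50.7% of the variance of log2 CPM) placed mA3 tumour 1 and 2 at 102 and 81.3, and vector tumour 9 at 60.7. Vector tumour 1 lay at -31.8, near the adjacent libraries, which ran from -61.2 to -42.5. Across genes, which are not independent replicates, vector tumour 1 correlated at 0.959 with mA3 adjacent 1 and at 0.912 with vector tumour 9. The libraries of a group correlated at 0.930 (vector adjacent), 0.912 (vector tumour), 0.961 (mA3 adjacent) and 0.973 (mA3 tumour).

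**Figure D2:**
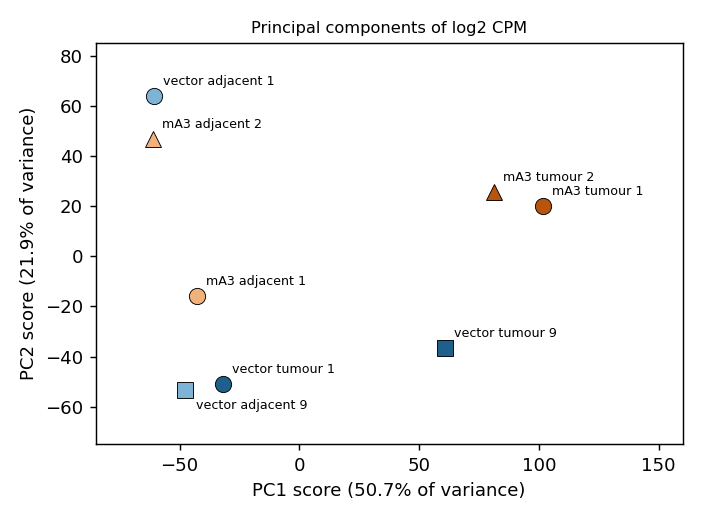
Scores of the 8 libraries on principal components 1 and 2 of log2 CPM, in score units; each point is a library, coloured by group and shaped by mouse number. Vector tumour 1 lies at -31.8 on component 1, between the adjacent libraries and vector tumour 9 at 60.7.

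Tumour was compared with adjacent liver over both plasmids (n = 4 libraries per group) to ask which genes mark these DEN-induced tumours. Akr1c18, an aldo-keto reductase that inactivates progesterone (ENSMUSG00000021214, chromosome 13, 4132615 to 4150654), rose by 5.09 ± 0.48 on the log2 scale (SE, edgeR adjusted p = 0.0129). Prom1, a membrane protein of progenitor cells also called CD133 (ENSMUSG00000029086, chromosome 5, 43993620 to 44102032), rose by 3.69 ± 0.30 (adjusted p = 0.0129). The fetal serum protein gene Afp rose by 3.35 ± 0.38 and the Golgi protein gene Golm1 by 3.38 ± 0.42 (adjusted p = 0.0139 each). Gpc3, a cell-surface proteoglycan used as a marker of hepatocellular carcinoma, went from 1.03 to 3.29 CPM in adjacent libraries to 9.11, 242, 127 and 794 CPM in vector tumour 1 and 9 and mA3 tumour 1 and 2 (adjusted p = 0.0236). Among falling genes, Cyp7b1, a hydroxylase of oxysterols and steroids, changed by -3.99 ± 0.83 (adjusted p = 0.0406, or 0.0585 with the mouse as a block). The fatty acid elongase gene Elovl3 changed by -3.99 ± 0.68 (adjusted p = 0.0249).

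Of 15009 genes, 442 rose and 254 fell, 696 in all, and 3366 had an unadjusted p under 0.05 (1781 higher and 1585 lower). The excess of rises was smaller under other tools, with 1027 rising and 844 falling in DESeq2, 249 and 209 in limma-voom, and 512 and 367 with the mouse as a block. The genes with the largest rises were Spink1, Gpc3, Cdh17, Erich4, Cacna1b, Rasal1, Igdcc4, Klrb1b, Csn3 and Wfdc15b, at log2 differences from 5.78 to 7.89. Several of these were near 0 in adjacent liver. Spink1 was at most 0.115 CPM in vector tumour 1 and all adjacent libraries and reached 44.9 CPM in vector tumour 9. Cdh17 was at most 0.172 CPM there and reached 94.8 CPM in mA3 tumour 1. The largest falls, from -5.33 to -3.48, were in Moxd1, Dct, Cyp7b1, Elovl3, Sult2a7, Mup9, Mup13, Mup18, Ugt1a9 and Mup11. The Mup and Ugt1a genes share sequence with close copies. The count depended on single libraries. It was 240 without vector adjacent 1, 1622 without vector tumour 1, 260 without vector tumour 9, 0 without mA3 adjacent 1 (3283 at an unadjusted p under 0.05), 0 without mA3 adjacent 2 (2252), 6 without mA3 tumour 1 and 136 without mA3 tumour 2. DESeq2 called 1871 genes in all and limma-voom 458.

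**Figure D3:**
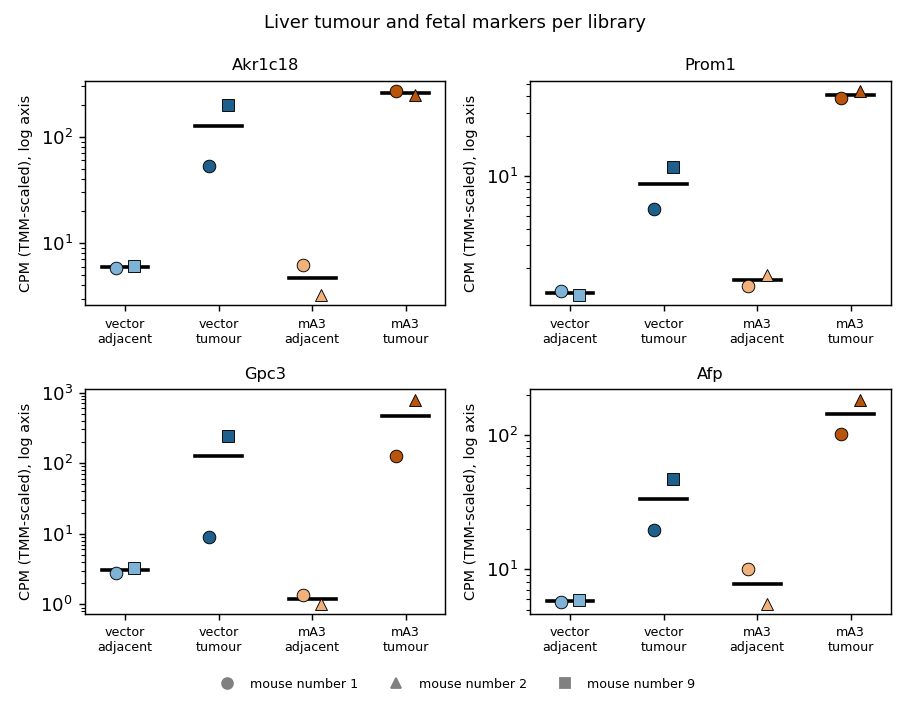
Levels of Akr1c18, Prom1, Gpc3 and Afp per library in TMM-scaled CPM on log axes; points are libraries shaped by mouse number and bars are group means of 2 libraries. All 4 tumour libraries lie above all 4 adjacent ones for each gene, with vector tumour 1 the lowest of the tumours.

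As lists, the tumour and fetal markers were higher in tumour (median log2 difference 2.28, 26 of 30 members above 0; adjusted p = 3.99e-10, or 0.255 with an estimated correlation). Over all genes 13 of the 30 rose, and adjusted over the list alone 19 rose and 1 fell. Cell-cycle genes lay above 0 in 39 of 40 members (median 1.49, or 0.93 without vector tumour 9; adjusted p = 9.25e-09, or 0.579 with an estimated correlation). Of these Ccne1, a cyclin of the entry into DNA synthesis, rose by 2.50 ± 0.55 (edgeR adjusted p = 0.045) and was the only member called over all genes. Adjusted over the list alone 22 rose. Cdk1, Melk and Aurkb had adjusted p-values of 0.0534, 0.0546 and 0.0548 over all genes. The unfolded protein response, which raises the protein-folding capacity of the endoplasmic reticulum, was higher as a list (22 members, median 0.61; adjusted p = 1.61e-05, or 0.255 with an estimated correlation). Its transcription factor genes Atf3 (3.14 ± 0.38, adjusted p = 0.0139) and Ddit3 (1.72 ± 0.29, adjusted p = 0.0249) and the pseudokinase gene Trib3 (3.05 ± 0.40, adjusted p = 0.0152) rose. These 3 were the members called over all genes, and 6 rose when adjusted over the list alone.

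Several lists of hepatocyte metabolism were lower in tumour, while secreted plasma proteins (48 members, median 0.13; adjusted p = 0.644) and acute-phase genes (26 members, median -0.32; adjusted p = 0.196) were not called. Of the plasma proteins 4 rose and 4 fell over all genes, and 9 rose and 6 fell adjusted over the list alone. Of the acute-phase genes 1 rose and 2 fell, and 3 rose and 8 fell adjusted over the list alone. Alb, the albumin gene, chosen after its values were seen, differed by 1.55 ± 0.56 (adjusted p = 0.153). Ddc, which encodes an amino acid decarboxylase, fell by 2.52 ± 0.30 on the log2 scale (SE, edgeR adjusted p = 0.0139). Cth, Gnmt and Bhmt, of methionine and cysteine metabolism, fell too, with log2 differences of -1.85 ± 0.28, -2.60 ± 0.41 and -2.19 ± 0.35 (adjusted p = 0.0199, 0.0207 and 0.0222). The urea cycle and amino acid list had a median of -1.15, with 10 of 34 members falling over all genes and 20 adjusted over the list alone (list adjusted p = 3.8e-11, or 0.255 with an estimated correlation). Of 51 cytochrome P450 genes, which oxidise steroids and foreign compounds, 9 fell and 2 rose (median -1.80; adjusted p = 5.32e-11, or 0.255 with an estimated correlation). Adjusted over the list alone 32 fell and 4 rose. The 2 rising genes were Cyp2a4 (3.51 ± 0.40, adjusted p = 0.0139), which may share reads with close copies, and Cyp2b9 (3.80 ± 0.73, adjusted p = 0.0345). Cyp2c67 and Cyp2c39 fell, at -2.05 ± 0.34 and -2.78 ± 0.49 (adjusted p = 0.0244 and 0.0272). Genes with higher expression in male than in female liver had a median of -2.42 (-3.64 without vector tumour 1), with 1 of 26 above 0. Of them 5 fell over all genes, including Elovl3, Moxd1, Cyp7b1 and Ugt2b1 (-2.62 ± 0.53, adjusted p = 0.0385), and 19 adjusted over the list alone (list adjusted p = 6.85e-13, or 0.379 with an estimated correlation).

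Bile acid synthesis and transport genes had a median of -1.37, and 9 of 24 fell over all genes, including Scp2 (-1.75 ± 0.31, adjusted p = 0.0272), the uptake transporter gene Slc10a1 (-1.81 ± 0.36, adjusted p = 0.0359) and Hsd17b4 (-1.16 ± 0.23, adjusted p = 0.0366). Adjusted over the list alone 17 fell and 1 rose (list adjusted p = 9.72e-11, or 0.255 with an estimated correlation). Fatty acid oxidation genes had a median of -0.88, with 8 of 34 falling over all genes, among them Acot3 (-2.95 ± 0.52, adjusted p = 0.0262), Acot4, Eci1 and Acot1. Adjusted over the list alone 21 fell (list adjusted p = 9.72e-11, or 0.255 with an estimated correlation). All 51 nuclear genes of oxidative phosphorylation lay below 0, at a median of -0.51 (-0.33 without vector tumour 9), with 0 called over all genes and 0 adjusted over the list alone (list adjusted p = 9.72e-11, or 0.579 with an estimated correlation). The smallest p in that list was that of Atp5f1 (-0.89 ± 0.27, adjusted p = 0.0985). Markers of macrophages and of Kupffer cells, the resident macrophages of liver, had a median of -0.61. It was -0.38 without vector adjacent 9, -0.30 without vector tumour 1 and -1.01 without vector tumour 9. Clec4f, Folr2 and Timd4 fell, at -1.66 ± 0.32, -1.84 ± 0.35 and -2.47 ± 0.50 (adjusted p = 0.0334, 0.0345 and 0.0385), and were among the 4 members called over all genes. Adjusted over the list alone 7 fell and 2 rose (list adjusted p = 0.00157, 0.639 with an estimated correlation and 0.188 without vector tumour 1). Markers of bile duct and progenitor cells were higher as a list (21 members, median 0.47; adjusted p = 0.0107, or 0.255 with an estimated correlation). Prom1 and Spp1 were the 2 members that rose over all genes, and adjusted over the list alone 7 rose, including Sox4 (2.83 ± 0.71) and Sox9 (2.04 ± 0.53). Markers of stellate cells, fibroblasts and their matrix were higher (34 members, median 0.55; adjusted p = 0.0107, or 0.639 with an estimated correlation). Of these Col4a2 rose over all genes (1.93 ± 0.42, adjusted p = 0.0443), and 7 rose and 1 fell adjusted over the list alone. That list was not called without vector adjacent 9 (adjusted p = 0.124), vector tumour 9 (0.0895, median 0.31) or both (0.482, median 0.25). Markers of B and plasma cells were higher (23 members, median 0.60; adjusted p = 0.0122, or 0.6 with an estimated correlation), with Igha (2.67 ± 0.49, adjusted p = 0.0306) the only member called over all genes and adjusted over the list alone. Their adjusted p was 0.12 without mA3 adjacent 1 (median 0.34), 0.128 without mA3 tumour 2 (0.31), 0.0817 without vector adjacent 9 and 0.172 without vector tumour 1 (median 0.34), and the median was 0.91 without vector adjacent 1. In all, 14 lists were called higher and 11 lower of the 47 tested, and 0 with an estimated correlation. Lists for PRC2 (adjusted p = 0.368), DNA methylation (0.349), DNA repair (0.112) and interferon-stimulated genes (0.392) were not called.

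**Figure D4:**
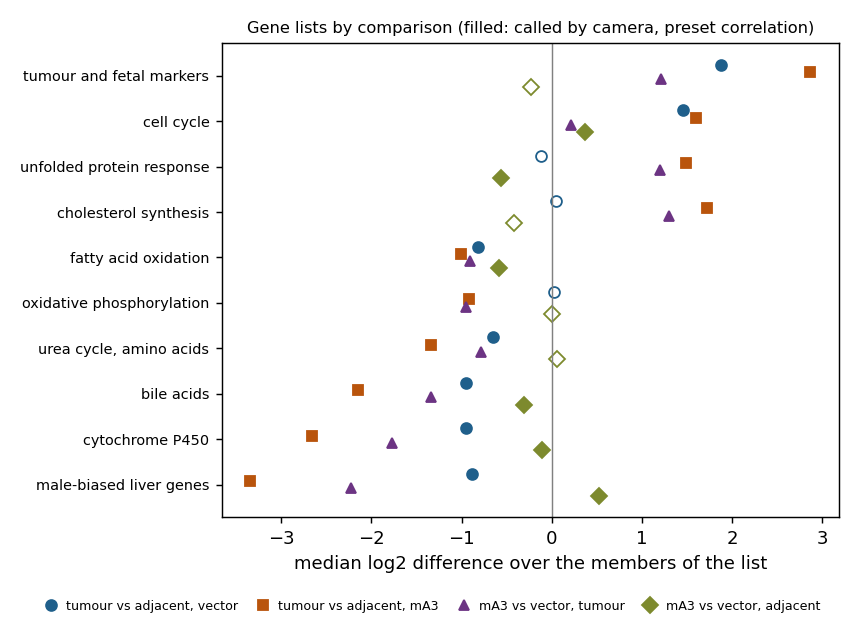
Median log2 difference over the members of 10 gene lists (horizontal axis) in 4 comparisons; filled symbols are lists called by camera with the preset correlation, open symbols are not called. In mA3 mice the medians of tumour against adjacent run from -3.34 (male-biased liver genes) to 2.87 (tumour and fetal markers).

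In vector mice alone, tumour was compared with adjacent liver (n = 2 libraries per group) to describe tumours without the added deaminase. Markers from the pooled comparison had the smallest p-values among higher genes. Akr1c18 held 53.5 and 200 CPM in tumours 1 and 9 against 5.82 and 6.12 CPM in adjacent liver, a log2 difference of 4.41 ± 0.66. Prom1 (2.72 ± 0.42), the secreted protease inhibitor gene Wfdc15b (5.34 ± 0.82), the semaphorin receptor gene Plxnb1 (2.07 ± 0.32) and the matrix protein gene Aebp1 (3.12 ± 0.51) were also higher. Lower were Nceh1 (-1.55 ± 0.31), Acot4 (-1.56 ± 0.33), Suox (-1.75 ± 0.38), Chpt1 (-2.02 ± 0.44) and Pros1 (-1.28 ± 0.28). None of these 10 passed (edgeR adjusted p = 0.435 each). edgeR called 0 genes, with 1397 at an unadjusted p under 0.05, and 142 without vector tumour 1. DESeq2 called 229, limma-voom 0 and limma on log2 FPKM 0.

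Tumour and fetal markers were nevertheless higher as a list (median 1.88, 22 of 30 above 0). The median was 0.55 without vector tumour 9 and 1.09 without both libraries of vector mouse 9. Over all genes 0 members were called, and adjusted over the list alone 8 rose, with Akr1c18, Prom1, Afp (2.52 ± 0.52) and Golm1 (2.41 ± 0.57) first (list adjusted p = 4.65e-05, 0.631 with an estimated correlation and 0.0526 without both libraries of vector mouse 9). Lower lists were fatty acid oxidation (median -0.81; adjusted p = 3.27e-09, or 0.631 with an estimated correlation), with Acot4, Acot1 (-2.84 ± 0.76) and Acadvl (-1.42 ± 0.42) among its smallest p-values, bile acids (-0.96; 4.66e-06, or adjusted p = 0.631 with an estimated correlation) and urea cycle and amino acids (-0.65; 2.4e-05, or adjusted p = 0.631 with an estimated correlation). The medians were -0.49 for fatty acid oxidation without vector adjacent 9, -0.62 for bile acids without vector adjacent 1, and -0.40 and -1.05 for urea cycle and amino acids without vector adjacent 1 and vector tumour 1. For these 3 lists 0 members were called over all genes and 0 adjusted over the list alone. Cell-cycle genes were higher in 36 of 40 members (median 1.46; 0 called over all genes and 0 adjusted over the list alone). Their adjusted p was 4.53e-07, or 0.725 with an estimated correlation, 0.0585 without vector tumour 9 (median 0.32) and 0.102 without both libraries of vector mouse 9 (median 0.55). The unfolded protein response was not called (median -0.12, mean 0.05; adjusted p = 0.548), with 0 members called over all genes and 1, Atf3 (2.55 ± 0.54), adjusted over the list alone. Oxidative phosphorylation was not called either (adjusted p = 0.0759). Its median was 0.02, while its mean was -0.13 and camera's direction was down. In all, 9 lists were called higher and 8 lower (17, or 10 without vector tumour 9), and 0 with an estimated correlation. With the mouse as a block, p53 targets (adjusted p = 0.00429) and interferon-stimulated genes (0.0453) were called as well. Their adjusted p was 0.741 each with an estimated correlation and no block, and 0.661 and 0.922 without both libraries of vector mouse 9.

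In mA3 mice, tumour was compared with adjacent liver (n = 2 libraries per group) in the same way. Among the largest rises, Cpe, a carboxypeptidase that processes hormones, went from 1.70 and 1.58 CPM to 379 and 179 CPM (7.40 ± 1.10, edgeR adjusted p = 0.0343). Bhlha15, a transcription factor gene of secretory cells, rose by 6.15 ± 0.83 (adjusted p = 0.0334), and Akr1c18 by 5.77 ± 0.71 (adjusted p = 0.0334). Cdh17, an intestinal cadherin, went from 0.131 and 0.0686 CPM to 94.8 and 41.4 CPM (adjusted p = 0.0334). Among falling genes, G6pc, which releases glucose from the liver, fell by 4.61 ± 0.80 (adjusted p = 0.0447), from 491 and 166 CPM to 6.35 and 20.6 CPM. The growth factor gene Igf1 (ENSMUSG00000020053, chromosome 10, 87858265 to 87937042) fell by 3.91 ± 0.62 (adjusted p = 0.0382), from 693 and 761 CPM to 46.4 and 50.3 CPM.

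In mA3 mice 118 genes rose and 60 fell, 178 in all, and 3002 had an unadjusted p under 0.05 (1540 higher and 1462 lower). The excess of rises was smaller under several alternatives, with 805 rising and 751 falling in DESeq2, 65 and 46 in limma-voom, 317 and 243 with the mouse as a block, 1080 and 983 without a filter, and 1157 and 1112 with only the groups compared. The other large rises were in Igdcc4, Cdhr2, Slc24a3, Wfdc15b, Gldn and Fhl3, and the other large falls in Dct, Elovl3, Mup11, Mup18, Wfdc21, Csrp3, Plekhb1 and Slco2b1. With any 1 of the 4 mA3 libraries left out the count was 0 in edgeR, with 2231, 1773, 1584 and 1791 genes at an unadjusted p under 0.05. It was 308 without vector adjacent 9, 1090 without vector tumour 1 and 1074 without vector tumour 9, libraries outside this comparison that enter through the shared spread, the scaling and the filter (15663, 15675 and 15704 genes tested). With the mouse as a block 560 genes were called, 175 of them among the 178. DESeq2 called 1556 and limma-voom 111.

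The unfolded protein response was higher in the libraries labelled mA3 tumour in 22 of 22 members (median 1.49; adjusted p = 1.89e-11, or 0.0723 with an estimated correlation). Trib3 rose by 4.82 ± 0.61 (edgeR adjusted p = 0.0334), Atf3 by 3.74 ± 0.54 (0.0334), Ddit3 by 2.65 ± 0.43 (0.0402) and the chaperone gene Hspa5 by 2.22 ± 0.38 (0.0437). These 4 were called over all genes and 13 rose adjusted over the list alone. Tumour and fetal markers were higher (median 2.87, 27 of 30 above 0; adjusted p = 1.44e-11, or 0.235 with an estimated correlation). Of them 7 rose over all genes, including Prom1 (4.66 ± 0.44), Abcc4 (2.71 ± 0.34) and Afp (4.19 ± 0.56), and 18 rose and 1 fell adjusted over the list alone. Urea cycle and amino acid genes were lower (median -1.34; adjusted p = 5.79e-14, or 0.235 with an estimated correlation). Of these, 4 fell over all genes, namely Ddc (-3.14 ± 0.44), Bhmt (-3.28 ± 0.51), Gnmt (-3.45 ± 0.60) and Cth (-2.27 ± 0.40), and 19 adjusted over the list alone. Male-biased liver genes were lower (median -3.34; 1 called over all genes, 21 adjusted over the list alone). The list's adjusted p was 4.84e-15, or 0.32 with an estimated correlation. All 51 nuclear genes of oxidative phosphorylation lay below 0 (median -0.92; 0 called over all genes and 0 adjusted over the list alone). The smallest p-values there were those of Cox7b, Ndufa4 and Cox6c, at log2 differences of -1.34 ± 0.38, -1.49 ± 0.42 and -1.52 ± 0.45, and the list's adjusted p was 3.2e-15, or 0.387 with an estimated correlation. Cholesterol synthesis was higher in 22 of 24 members (median 1.72; 0 called over all genes and 0 adjusted over the list alone; adjusted p = 2.55e-05, or 0.599 with an estimated correlation). In all, 12 lists were called higher and 11 lower, and 0 with an estimated correlation. With the mouse as a block canonical NF-kB genes were called as well (adjusted p = 0.0269, or 0.676 with an estimated correlation and no block).

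The tumours of mA3 mice were compared with those of vector mice (n = 2 libraries per group) to ask what the plasmid changes in tumour. The smallest p was that of Abcc4, an exporter of cyclic nucleotides and bile acids (ENSMUSG00000032849, chromosome 14, 118482692 to 118706219). It held 34.6 and 38.6 CPM in the libraries labelled mA3 tumour and 4.24 to 6.98 CPM in the other 6 (2.99 ± 0.34). Also higher were the phosphatase gene Dusp4 (2.82 ± 0.45), the lipid receptor gene Lpar2 (1.87 ± 0.31), the carbonyl reductase gene Cbr3 (4.85 ± 0.82) and Prom1 (2.25 ± 0.39). Lower were the glutamate transporter gene Slc17a8 (-3.36 ± 0.47), the lipid droplet gene Plin5 (-2.91 ± 0.48), Bhmt (-2.98 ± 0.51), Retsat (-2.65 ± 0.46) and Spata22 (-2.04 ± 0.35). None of these passed (edgeR adjusted p = 0.268). edgeR called 0 genes, with 2127 at an unadjusted p under 0.05. The count was 270 without vector tumour 9 and 1748 without both libraries of vector mouse 9. DESeq2 called 477 and limma-voom 0.

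The unfolded protein response was higher in 21 of 22 members (median 1.20; adjusted p = 1.51e-09, or 0.0931 with an estimated correlation). Over all genes 0 members were called, and adjusted over the list alone 11 rose, led by Sdf2l1 (1.49 ± 0.26), Hspa5 (2.08 ± 0.38), Trib3 (2.85 ± 0.56) and Pdia4. Tumour and fetal markers were higher in 24 of 30 (median 1.21, or 2.35 without vector tumour 9; 0 called over all genes and 6 adjusted over the list alone; adjusted p = 5.91e-07, or 0.355 with an estimated correlation). Genes of the NRF2 response to oxidants were higher (median 0.86, or 0.08 without mA3 tumour 1), with Abcc4, Cbr3, Srxn1 (2.87 ± 0.52) and Slc7a11 (4.25 ± 0.92) first. In that list 0 members were called over all genes and 5 adjusted over the list alone, and its adjusted p was 3.41e-05, 0.668 with an estimated correlation, 0.125 without vector tumour 9 and 0.167 without both libraries of vector mouse 9.

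Respiratory chain genes were lower in the libraries labelled mA3 tumour. The 51 nuclear genes of oxidative phosphorylation had a median of -0.95, or -0.57 without vector tumour 1 (0 called over all genes and 21 adjusted over the list alone). Examples are Ndufa6 (-1.37 ± 0.37), Atp5h (-1.40 ± 0.38), Ndufa3 (-1.79 ± 0.50) and Uqcrq (-1.64 ± 0.45), and the list's adjusted p was 5.34e-12, or 0.668 with an estimated correlation. All 13 genes of the mitochondrial genome lay below 0 (median -1.86, or -1.14 without vector tumour 1; 0 called over all genes and 12 adjusted over the list alone), with mt-Nd4l at -1.98 ± 0.55. Nuclear copies share reads with some of them. The adjusted p was 1.59e-07, or 0.668 with an estimated correlation. Bile acid genes were lower (median -1.34, or -0.71 without vector tumour 1; 0 called over all genes and 11 adjusted over the list alone), with Nr0b2, a nuclear receptor gene that represses bile acid synthesis, at -1.89 ± 0.35 (list adjusted p = 1.96e-08, or 0.355 with an estimated correlation). Fatty acid oxidation was lower too (median -0.90; 0 called over all genes and 7 adjusted over the list alone), with Eci2 at -1.87 ± 0.33 (list adjusted p = 1.63e-07, or 0.355 with an estimated correlation). In all, 7 lists were called higher and 11 lower, and 0 with an estimated correlation. PRC2 genes (adjusted p = 0.863), DNA methylation (0.996), DNA repair (0.567) and T-cell exhaustion (0.812) were not called.

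Adjacent liver of mA3 mice was compared with that of vector mice (n = 2 libraries per group), where Apobec3 itself was higher. After Apobec3, higher genes included Tsc22d1 (1.56 ± 0.51), Inf2 (0.94 ± 0.32) and Sdc3 (1.16 ± 0.40). Slc17a8 (-1.65 ± 0.43), Plin5 (-1.58 ± 0.45), Retsat (-1.48 ± 0.44), Cyp4a10 (-4.52 ± 1.35) and Cyp4a32 (-1.30 ± 0.39) were lower. None of these passed (edgeR adjusted p = 1). Cyp4a10 was at 2690 CPM in vector adjacent 9 and at 154 CPM in vector adjacent 1, so that its difference rests mostly on mouse 9. Plin5 (108 against 39.6 CPM), Retsat (364 against 199 CPM) and Cyp4a32 (53.3 against 28.5 CPM) were also higher in vector adjacent 9 than in vector adjacent 1. Slc17a8 was not (19.1 against 23.2 CPM). edgeR called 0 genes, with 155 at an unadjusted p under 0.05. DESeq2 and limma-voom called 0 as well.

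Interferon-stimulated genes were higher in mA3 adjacent liver in 44 of 50 members (median 0.35, or 0.16 without mA3 adjacent 1 and 0.59 without vector adjacent 9), among them Zbp1 (1.27 ± 0.44), Isg15 (1.20 ± 0.45) and Oas3 (1.53 ± 0.57). The list's adjusted p was 1.34e-11, or 0.59 with an estimated correlation. Fatty acid oxidation was lower in 33 of 34 members (median -0.58), with Acot2 at -2.24 ± 0.68 and Acot1 at -2.43 ± 0.75 (list adjusted p = 2.54e-18, or 0.105 with an estimated correlation). The unfolded protein response was lower in 18 of 22 (median -0.56), with Creld2 at -1.28 ± 0.50, Dnajb9 at -1.08 ± 0.44 and Hspa5 at -0.73 ± 0.36 (list adjusted p = 1.31e-06, or 0.105 with an estimated correlation). Macrophage markers were higher in 26 of 30 (median 0.58), including Msr1 (0.86 ± 0.42) and Cd5l (1.09 ± 0.54). Their adjusted p was 1.05e-06, 0.803 with an estimated correlation and 0.542 without vector adjacent 1 (median 0.22). The median was 1.08 without vector adjacent 9. In each of these 4 lists 0 members were called over all genes and 0 adjusted over the list alone. In all, 9 lists were called higher and 8 lower, and 0 with an estimated correlation. The count of lists called was 10 without mA3 adjacent 1 and 11 without mA3 adjacent 2. Markers of B and plasma cells (median 0.58; list adjusted p = 0.000484) and of T and NK cells (median 0.38; 0.00147) were among the lists called higher. Neither call held with every library left out. Tumour and fetal markers were not called (median -0.23; adjusted p = 0.884).

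The interaction tested whether the difference between tumour and adjacent liver was the same in mA3 mice as in vector mice (2 mice each). Genes of protein folding in the endoplasmic reticulum differed as a list. Hspa5, the main chaperone of that compartment (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), was at 2520 and 2330 CPM in the libraries labelled mA3 tumour. It was at 584 and 566 CPM in vector tumours, 462 and 577 CPM in mA3 adjacent liver and 941 and 777 CPM in vector adjacent liver (interaction 2.80 ± 0.52). The disulfide isomerase gene Pdia4 (2.06 ± 0.44), Trib3 (3.53 ± 0.77) and the cochaperone gene Dnajb9 (2.56 ± 0.63) went the same way. Abcc4 (3.24 ± 0.47) and Rerg (2.53 ± 0.57) were also higher, and no single gene passed (edgeR adjusted p = 0.842 for each of these). Lower interactions were those of Leap2 (-3.21 ± 0.68), Fndc4 (-1.49 ± 0.36), Tifa (-1.74 ± 0.43), Nr0b2 (-1.90 ± 0.48), Apobec3 (-2.51 ± 0.83) and Adhfe1, with adjusted p-values of 0.842. edgeR called 0 genes, with 749 at an unadjusted p under 0.05. DESeq2 called 11 and limma-voom 0.

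As a list, the unfolded protein response had a positive interaction in 22 of 22 members (median 1.45), with 0 members called over all genes and 10 adjusted over the list alone. Its adjusted p was 6.71e-16, and it was the list called with an estimated correlation too (adjusted p = 0.0336). It was called with each of the 8 libraries left out, with adjusted p-values from 1.57e-20 to 3.35e-09. Oxidative phosphorylation had a negative interaction (median -1.01, or -0.58 without vector tumour 1; adjusted p = 1.83e-11, or 0.645 with an estimated correlation). Male-biased liver genes had 26 of 26 members below 0 (median -3.03, or -0.87 without vector tumour 1; adjusted p = 1.4e-08, or 0.645 with an estimated correlation). For these 2 lists 0 members were called over all genes and 0 adjusted over the list alone. Tumour and fetal markers had a median of 1.36 (2.28 without vector tumour 9), with 0 called over all genes and 1 adjusted over the list alone (list adjusted p = 4.17e-07, or 0.645 with an estimated correlation). Fatty acid oxidation was not called (median -0.18; adjusted p = 0.288). In all, 6 lists were called with a positive and 10 with a negative interaction. With the mouse as a block, genes of TGF-beta signalling and epithelial-mesenchymal transition were called as well (adjusted p = 0.0448). Without a block its adjusted p was 0.0502, 0.855 with an estimated correlation and 0.966 without vector tumour 1.

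**Figure D5:**
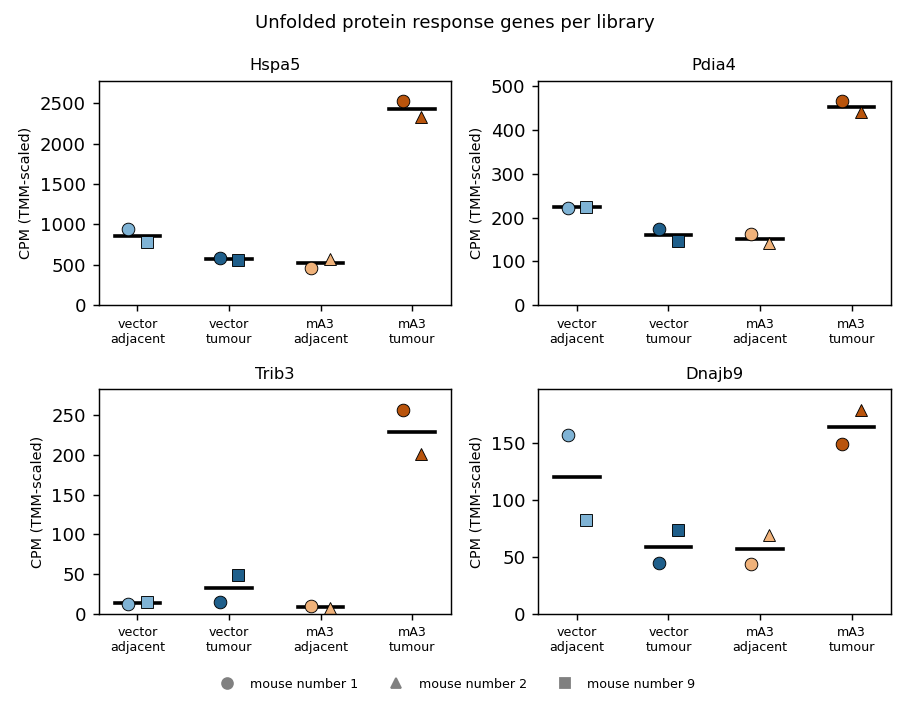
Levels of Hspa5, Pdia4, Trib3 and Dnajb9 per library in TMM-scaled CPM (linear axes from 0), by group; points are libraries shaped by mouse number and bars are means of 2 libraries. For Hspa5 the libraries labelled mA3 tumour, at 2520 and 2330 CPM, lie above the other 6, which reach 941 CPM.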

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

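The interaction tests were fixed before the data were examined, while the tests of explanations for Apobec3 and for the unfolded protein response, and the tests without vector mouse 9, were chosen after these results had been seen. Each result here is a difference between tumour and adjacent liver that was unlike in mA3 and vector mice.

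Apobec3 was lower in tumour than in adjacent liver in both mA3 mice (log2 changes of -2.04 and -1.17) and higher in both vector mice (1.38 and 0.59), an interaction of -2.51 (edgeR adjusted p = 0.842), or -1.83 without vector adjacent 1 and -3.71 without vector adjacent 9. A rise of immune cells in general as large as that of Apobec3 in the mA3 adjacent pieces is argued against. The highest median among 6 lists of immune markers was 0.58 there (SD of its members 0.51; 1.08 without vector adjacent 9), against 2.67 for Apobec3. All 6 medians were above 0. These broad lists cannot exclude more cells of a subset rich in Apobec3. Exchanged tumour and adjacent labels in the mA3 mice would put tumour and fetal markers in the libraries labelled adjacent, whereas that list was higher in the libraries labelled tumour, at a median of 2.87. What stays open is whether the tumours lost or never carried the plasmid or repressed its gene, which may be a property of tumour tissue in these 2 mice and was not tested.

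Genes of the unfolded protein response differed more between tumour and adjacent liver in mA3 mice than in vector mice, with higher levels in the libraries labelled mA3 tumour, at a median interaction of 1.45 over 22 members (adjusted p = 6.71e-16, or 0.0336 with an estimated correlation). Hspa5 and Pdia4 were lower in tumour than in adjacent liver in both vector mice and higher in both mA3 mice, with interactions of 2.80 and 2.06 (edgeR adjusted p = 0.842 each). Without vector tumour 1 the median was 1.33, which argues against that library's likeness to adjacent tissue as the sole source. Without both libraries of vector mouse 9 it was 1.37, which argues against that mouse's clock or feeding state as the sole source. Each of these fits keeps the other unusual library as the lone vector tumour, so that both sources together were not excluded. A state of the whole mouse would raise the list in mA3 adjacent liver too, where its median was -0.56. An effect of the plasmid may remain and so may a difference between individual tumours, which 2 mice per plasmid cannot separate, and Apobec3 itself was not higher in the libraries labelled mA3 tumour.

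Abcc4 was lower in tumour than in adjacent liver in both vector mice and higher in both mA3 mice (interaction 3.24, edgeR adjusted p = 0.842). Nr0b2 was higher in tumour in both vector mice and lower in both mA3 mice (interaction -1.90, edgeR adjusted p = 0.842).

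Some lists of hepatocyte metabolism and the mitochondrial lists had negative interactions. Other hepatocyte lists were not called, namely secreted plasma proteins (adjusted p = 0.887), acute-phase genes (0.761), female-biased liver genes (0.594), gluconeogenesis (0.609), lipogenesis (0.384), fatty acid oxidation (0.288) and hepatocyte transcription factors (0.115). The medians of those called were -3.03 for male-biased liver genes, -1.31 for cytochrome P450 genes, -1.19 for bile acid genes and -0.87 for urea cycle and amino acid genes. They were -1.01 for nuclear genes of oxidative phosphorylation and -1.39 for genes of the mitochondrial genome, while tumour and fetal markers had 1.36. Without vector tumour 1 they were -0.87 for male-biased genes, -0.49 for cytochrome P450, -0.45 for bile acids, -0.58 for oxidative phosphorylation and -0.71 for the mitochondrial genome. Tumour and fetal markers had 2.28 without vector tumour 9. Without both libraries of vector mouse 9, cytochrome P450 had -2.20, the mitochondrial genome -2.37 and tumour markers 2.30. These 7 lists were called with each library left out, and their adjusted p with an estimated correlation was 0.645 or, for the mitochondrial genome, 0.667.

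Directions turned here are those of camera, which compares a list with all other genes. Cholesterol synthesis genes had a median interaction of 1.73, with an adjusted p of 0.785 and the direction turned to down without vector adjacent 1 (median -0.36), and 0.284 without vector tumour 9. Their median was 2.62 without vector adjacent 9 and 2.68 without vector tumour 1. NRF2 targets had 0.78 (0.14 without mA3 tumour 1, 0.25 without vector adjacent 1), with an adjusted p of 0.0735 without mA3 tumour 1, 0.274 without vector tumour 9 and 0.206 without both libraries of vector mouse 9. Liver targets of Wnt and beta-catenin had -2.40 (-0.73 without vector tumour 1, adjusted p = 0.093). Ribosomal protein genes had -0.38, with -0.64 and 0.09 without mA3 adjacent 1 and 2 (adjusted p = 0.427, turned to up, without mA3 adjacent 2, 0.265 without vector tumour 9 and 0.401 without both libraries of vector mouse 9). For p53 targets the median was 0.44 (adjusted p = 0.93, turned to down, without vector tumour 1, 0.422 without vector adjacent 9 and 0.187 without mA3 adjacent 2). For immediate early genes it was 0.41 (adjusted p = 0.305, turned to down, without vector tumour 1, 0.536 without vector adjacent 9, 0.238 without mA3 adjacent 2 and 0.0719 without mA3 tumour 2). Without vector tumour 1 and vector tumour 9 the medians were 0.11 and 1.41 for p53 targets and -0.16 and 1.66 for immediate early genes. Without vector adjacent 9 they were -0.05 and 0.17, and without mA3 adjacent 1 they were 0.75 and 0.90. For p53 targets the median was also 0.28 without mA3 adjacent 2 and 0.23 without mA3 tumour 1. Genes of red blood cells had -1.15 (adjusted p = 0.203 without mA3 adjacent 2, 0.248 without mA3 tumour 2, 0.0812 without vector adjacent 9, 0.284 without vector tumour 9 and 0.239 without both libraries of vector mouse 9). Their median was -0.06 without vector tumour 9, -0.58 without mA3 tumour 2, -0.74 without vector adjacent 1 and -1.79 without mA3 tumour 1. Genes of adipose tissue, muscle and kidney had -1.80, with an adjusted p of 0.0487. It was 0.0932 and 0.0661 without mA3 adjacent 1 and 2, 0.0541 without mA3 tumour 2, 0.103 and 0.117 without vector adjacent 1 and 9, and 0.0503 without vector tumour 1 (median -0.88). With an estimated correlation, these 8 lists had adjusted p-values from 0.645 to 0.89.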

How the results depend on the processing

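Fits without both libraries of vector mouse 9 and the list tests with a library left out were chosen after the data were seen. Other alternatives were fixed before the data were examined.

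The gene count for tumour against adjacent liver over both plasmids (696 in edgeR) was 2450 without a filter, 1871 in DESeq2, 458 in limma-voom, and from 0 (without mA3 adjacent 1 or mA3 adjacent 2) to 1622 (without vector tumour 1) with a library left out. In vector mice the count of 0 became 674 without a filter, 229 in DESeq2, and from 0 to 142 (without vector tumour 1). In mA3 mice the count of 178 became 99 with upper-quartile factors, 2063 without a filter, 79 with a mean of at least 5 CPM, 1556 in DESeq2, 111 in limma-voom, 2269 with only the groups compared, 331 on log2(FPKM + 1), 2196 without vector mouse 9, and from 0 (with any 1 of the 4 mA3 libraries left out) to 1090 (without vector tumour 1). The cause was not tested. For mA3 against vector tumours the count of 0 became 1084 without a filter, 477 in DESeq2, 1748 without vector mouse 9, and from 0 to 270 (without vector tumour 9). In adjacent liver the count of 0 became 56 without a filter. The interaction count of 0 became 316 without a filter and 11 in DESeq2. Of these counts, 80 values under alternatives stayed within 1.5 times, 22 were higher and 14 lower. Most of the 80 were counts of 0 that stayed 0. All 14 lower values were in the comparisons that called genes, over both plasmids and within mA3 mice.

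With the mouse as a block, 560 genes were called in mA3 mice and 879 over both plasmids. The block ended the call of Cyp7b1 over both plasmids and added p53 targets and interferon-stimulated genes in vector mice, canonical NF-kB genes in mA3 mice and the TGF-beta list in the interaction. It changed no other call of a list or of a gene named for its change.

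With an estimated correlation, 0 of the 47 lists were called in each comparison except the interaction, with 1 (unfolded protein response). fry called 9 over both plasmids, 0 in vector mice, 9 in mA3 mice, 1 between tumours, 0 in adjacent liver and 1 in the interaction. The next counts include lists called only with libraries left out. In vector mice the count of 17 became 10 without vector tumour 9, 22 without vector tumour 1 and 5 without both libraries of vector mouse 9. Between adjacent groups the count of 17 became 10 to 17, lowest without mA3 adjacent 1. Of the 17 lists called in vector mice, 4 were called with each of the 8 libraries left out. Of the 17 between adjacent groups, 3 were.

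The Apobec3 difference kept its direction in all but 3 cases. Over both plasmids it ran from -0.71 (without vector adjacent 1) to 0.22 (without vector adjacent 9) with a library left out. Between tumours it ran from -0.23 (without vector tumour 1) to 0.73 (without vector tumour 9) and was -0.12 without mA3 tumour 2. The cause was not tested. In mA3 mice the tumour difference passed without a filter (-1.63), with only the groups compared (-1.66) and without both libraries of vector mouse 9 (-1.63). Between adjacent groups (2.71) and in the interaction (-2.52) it passed without a filter. Under the other 102 combinations of comparison and alternative, Apobec3 stayed on its side of the threshold.

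Of the values of single named genes under alternatives, 1154 kept their direction and side of the threshold, 71 passed only under the alternative and 245 only in the analysis reported. No named gene other than Apobec3 reversed. The biological coefficient of variation was 39.1%, and genes of few counts carry counting error on top of it.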

Other observations

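The tests of explanations for vector tumour 1 and the genes of the clock and feeding were chosen after the values had been seen, while the count over other splits of the libraries was fixed before the data were examined.

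Over both plasmids, tumours also differed in lists not described above. Immediate early genes were higher (median 1.45, or 0.44 without vector tumour 9 and 0.76 without both libraries of vector mouse 9; 3 of 23 members rose over all genes and 10 adjusted over the list alone), with Egr1 at 4.17 ± 0.63 (edgeR adjusted p = 0.0199) and Ier2 at 1.18 ± 0.25 (0.044). The list's adjusted p was 6.61e-05, or 0.579 with an estimated correlation. Genes of MHC class I and antigen processing were higher (median 0.42, or 0.70 without vector adjacent 1; 3 of 20 rose over all genes and 6 adjusted over the list alone), with H2-Q6, which may share reads with close copies, at 1.83 ± 0.23 (adjusted p = 0.0142). That list's adjusted p was 0.000419, or 0.28 with an estimated correlation. Targets of p53 were higher (median 0.84, or 0.36 without vector tumour 9; 3 of 26 rose over all genes and 7 adjusted over the list alone), with Phlda3 at 2.68 ± 0.48 (adjusted p = 0.0283) and Zmat3 at 1.41 ± 0.29 (0.0385). The list's adjusted p was 0.00119, or 0.579 with an estimated correlation. Liver targets of Wnt and beta-catenin, which mark hepatocytes around the central vein, were lower (median -1.20, or -1.81 without mA3 tumour 2 and -2.09 without vector tumour 1; 2 of 17 fell over all genes and 6 adjusted over the list alone). Axin2 was at -1.97 ± 0.44 (adjusted p = 0.0481) and Oat at -3.35 ± 0.76 (0.0497), and the list's adjusted p was 6.65e-06, or 0.568 with an estimated correlation.

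Vector tumour 1 lay near the adjacent libraries. On a scale from the adjacent mean (0) to the tumour mean (1) of the other libraries, it lay at a median of 0.0716 over 943 genes that rise and 0.311 over 673 that fall without it. A label exchange with vector adjacent 1 is argued against, since vector adjacent 1 lay at a median of -0.0075 (interquartile range 0.181) between the other 3 adjacent libraries and the other 3 tumours, over 1110 genes rising in a fit without both libraries of that mouse. Dilution of the tumour piece with adjacent tissue could not be decided. It would place rising and falling genes at equal medians, and these were 0.0716 and 0.311, with wide interquartile ranges (0.227 and 0.755). Macrophage markers were at 0.608 of their level in vector adjacent 1 (0.695 at 1 SE above), while dilution needs 0.689 or more. Of these markers, 20 of 30 were lowest of the 8 libraries in vector tumour 1 (12.5% by chance). An adjacent piece labelled as tumour could not be decided either: vector tumour 1 exceeded 3 adjacent libraries in 51.8%, 57.6%, 59.3% and 53.5% of rising genes, against 29.8%, 40.3%, 45.1% and 19% for vector adjacent 1 and 9 and mA3 adjacent 1 and 2 left out in turn, and it may be a tumour closer to normal liver, but adjacent libraries themselves ranged from 19% to 45.1%.

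Over all 35 splits of the 8 libraries into 4 and 4, fitted as 2 groups, the split into tumour and adjacent called 438 genes and 1 split, the real one, gave as many. The highest other split gave 49. Because tumour and adjacent libraries are paired by mouse, the splits to compare are the 8 that part the libraries of all 4 mice, and the highest other of these gave 0. With 8 splits the smallest share is 12.5%, too large to go under 0.05. The remaining splits keep both libraries of some mice together.

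Both libraries of vector mouse 9 differed from the other 6 in genes of the circadian clock. Dbp was at 2.43 and 2.54 CPM in the adjacent and tumour library of that mouse, against 107 to 207 CPM elsewhere. Arntl was at 29.0 and 38.3 CPM against 0.803 to 4.35 CPM, and Per3 at 4.55 and 5.80 CPM against 33.6 to 124 CPM. Both libraries lay outside the range of the other 6 in 11 of 13 clock genes, Per1 and Per2 being the exceptions, against 9.31% of all genes (7.14% by chance). The fat synthesis gene Fasn was at 55.8 and 74.6 CPM against 259 to 1221 CPM, and Pdk4, which is raised by fasting, at 48.7 and 22.2 CPM against 2.06 to 5.84 CPM. The labels give no time of day or feeding state.

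Neat1 and Ccnl1, chosen after their values were seen, were low in vector adjacent 1 and mA3 adjacent 2. Neat1 was at 56.5 and 117 CPM there, against 578 CPM or more in the other libraries, and Ccnl1 was at 25.3 and 24.5 CPM against at least 47.0 CPM. Meg3, Clk2, Pnisr, Leng8 and Firre were also lowest in these libraries, for example Pnisr at 36.4 and 37.1 CPM against at least 89.4 CPM. All these genes were chosen after the values were seen, as transcripts retained in the nucleus. The libraries are of different mice and plasmids, yet correlated at 0.981, the highest of any pair. They lay at 64.0 and 46.8 on the component that holds 21.9% of the variance. No tumour library was as low, so the pattern enters comparisons of tumour with adjacent liver. Its cause was not tested.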
